A study of Mus musculus with 36 samples.

How the data were processed

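The study measured RNA from whole male mouse embryos of the inbred strain C57BL/6J with an Illumina expression array, a bead array that reads each probe as 1 fluorescence value. Embryos were collected 9.5 days post coitum, after their mothers had chosen to drink water, 10% ethanol or nicotine at 100 µg/ml during days 0.5 to 8.5. There were 12 embryos in each of 3 groups, and 1 array per embryo, 36 arrays in all. The group and the replicate number of each embryo came from the sample titles. The labels do not say which embryos shared a mother, a day or a slide, so the tests treat the embryos as independent. The p-values of single probes measure the spread between these embryos.

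The authors' deposited values are intensity on a linear scale, 1 per probe and embryo, made with GenomeStudio 1.9.0 per the submitters' processing notes. The background correction and the normalization are not given in the sources used here. From the values themselves, every array had nearly the same distribution: the median intensity was 10.7 to 10.8, the mean 357.7, the highest value 18147.3 and the lowest 1.69. Such equal distributions are what quantile normalization gives, and no value was at or below 0. A further file of signals before normalization names its 72 signal and detection columns by running numbers that match no sample label, so those columns were not used. For that reason the background correction planned before the data were examined could not be run, and the test started from the deposited intensity. As the values were already alike between arrays, no further normalization was applied. No total count exists for an array, and the number of arrays limits the precision.

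From the deposited intensity, log2(intensity + 16) was computed, so a log2 difference here understates the change of dim probes. A probe was kept if its intensity reached 32 on at least 12 of the 36 arrays, which left 16927 of 45281 probes. This filter was set after the detection values proved unusable and before any group was compared. Gene symbols came from the platform annotation supplied for the array: 34885 probes had 1 symbol, 18 had several and 10378 were unnamed there. Of the kept probes 14690 had 1 symbol, covering 9683 genes, and the kept probe with the highest mean level stood for its gene.

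Each pair of groups was compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on all 36 arrays with a mean per group and 33 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the kept probes, and the threshold was an adjusted p of 0.05. Before the data were examined, 36 lists of genes for pathways, cell types and embryonic stage were fixed, together with the tests and the rule for named genes. The 30 lists with at least 5 measured genes, other than the sex check, were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera compares the genes of a list with the other genes. At the preset correlation its p-value therefore does not measure how much the list mean varies between embryos. Camera with a correlation estimated from the residuals and fry, also in limma, were alternatives. The spread between embryos was compared with a permutation test of 100000 resamples.

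Replicate numbers 1 to 12 occur in each group of the labels, so a second fit with replicate number as a block was fixed in advance, with 22 residual degrees of freedom. Deviations from the group means correlated above 0.1 in all 36 same-number pairs (mean 0.589, lowest 0.243), against a mean of -0.0633 for other pairs. By the criterion set beforehand the numbers therefore count as pairs, as a property of the data and not of the labels. Most of this came from 2 sets of numbers, 1 to 6 and 7 to 12. Arrays of the same set with another number already correlated at a mean of 0.464, so the criterion does not separate 12 pairs from 2 sets. Among arrays of the other groups, 12 of the 36 arrays correlated best with their own number. After the means of the sets were removed, 6 of the 36 did so. The correlation was then above 0.1 in 18 of the 36 pairs, with a mean of 0.138. Blocked values stand beside each result whose call they change.

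Named genes followed a fixed rule. It took up to 10 higher and 10 lower genes past the threshold in a comparison, by size of change, and the 10 genes of smallest unadjusted p where fewer than 10 passed. It also took up to 4 members past the threshold and the 2 of smallest p from each list reported, the sex check genes, and a short set of genes of alcohol and nicotine biology. The rule was applied to the blocked fit as well. Other probes of a named gene were looked at, and disagreement is stated.

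The steps were tested on simulated data for nicotine against control, with 50 probes changed at each size among 16927. Without the block 38% of probes changed by 0.4, 56% by 0.6, 90% by 1 and 98% by 1.5 on the log2 scale were recovered, and 0 of 16727 unchanged probes were called. With the block the shares were 70%, 82%, 100% and 100%, and 10 unchanged probes were called. In a simulation of ethanol against control, a shift of -0.2 of the cholesterol synthesis list was recovered and 0 other lists were called. The observed shift of that list was smaller, at -0.14. The simulated noise was drawn separately for each probe, without the residual correlation between genes of the real arrays. The simulations therefore cannot tell how often unchanged probes or lists would be called in the real arrays. Alternatives covered the normalization between arrays, the filter, the offset, array weights, the variance model, a residual component as a covariate, 1 probe per gene, left-out embryos, the sets of replicate numbers and the set test. Tables were handled with the data.table package (1.17.8) and figures drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.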

Results

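The data describe the RNA of 36 whole male embryos, 12 from mothers given water (Control), 12 from mothers that drank ethanol and 12 from mothers that drank nicotine. At 9.5 days post coitum the mouse embryo has a closing neural tube, a beating heart and a growing tail bud. Of the genes on the array, 9683 had a probe above the intensity minimum. Differences below are log2 differences of group means with standard errors (SE), and n = 12 embryos per group unless stated.

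Among the embryos the largest division did not follow the drink. Replicates 1 to 6 and 7 to 12 of all 3 groups lay apart on the first principal component, which held 48.1% of the variance, and 10972 of 16927 probes (64.8%) differed between these sets at an adjusted p of 0.05 (limma). The embryos numbered 6 of each group lay apart from the others on component 2. Genes of the Y chromosome were present in all embryos, as the label male requires: Eif2s3y had a mean log2 level of 8.62 ± 0.74 (SD) in Control, 8.62 ± 0.85 in Ethanol and 8.72 ± 0.87 in Nicotine, and Kdm5d 7.10 ± 0.53, 7.24 ± 0.60 and 7.20 ± 0.68.

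**Figure D1:**
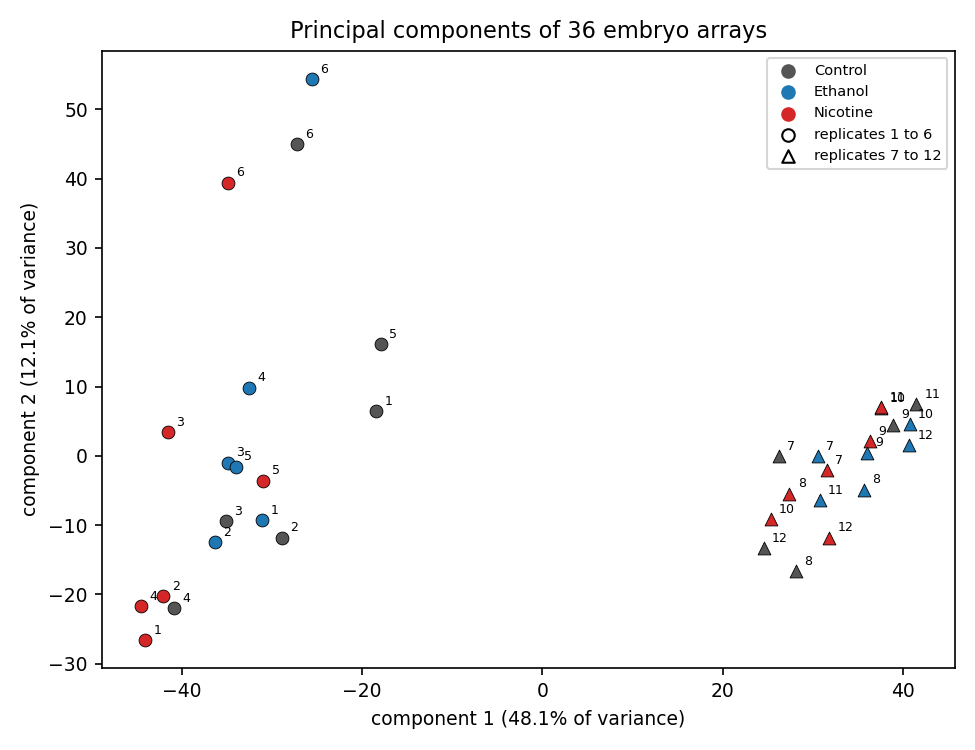
Each point is 1 of the 36 embryo arrays on the first and second principal components of the kept probes (axes in component units, 48.1% and 12.1% of the variance), coloured by group and numbered by replicate. Replicates 1 to 6 lie between -44.5 and -17.9 on component 1 and replicates 7 to 12 between 24.5 and 41.4, and the replicates numbered 6 lie between 39.4 and 54.4 on component 2.

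The comparison of ethanol with control asks what maternal ethanol before mid-gestation left behind in the embryo's RNA. The genes of cholesterol synthesis were lower as a list after ethanol. All 15 measured members were below control, by a list mean of -0.14 (SD of the 12 pair differences 0.12), and the list was lower in 10 of 12 pairs of equal replicate number. Lss, which closes the sterol ring as lanosterol synthase, differed by -0.17 (SE 0.0808; its other probe by 0.01, so the probes disagree) and Hsd17b7, a later enzyme of the pathway, by -0.13 (SE 0.0557). Camera gave an adjusted p of 4.01e-09 at the preset correlation, and the list passed with adjusted p = 0.0144 with an estimated correlation. With replicate number as a block, camera gave 7.45e-10, but adjusted p = 0.205 with an estimated correlation. The list did not pass with fry (adjusted p = 0.435, and 0.318 with the block) or with an exact sign-flip test of the pairs (adjusted p = 0.103). The mean was -0.15 in replicates 1 to 6 and -0.13 in replicates 7 to 12.

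No single member of the cholesterol list passed. The number of members that changed was 0 over all genes and 0 adjusted over the list alone (limma). With the block the count was 0 over all genes and 2 adjusted over the list alone, namely Mvd, mevalonate diphosphate decarboxylase, at -0.21 (SE 0.136 without the block) and Insig1, a sterol-regulated inhibitor of the pathway, at -0.27 (SE 0.312 without the block). Mvd and Insig1 are named after their values were seen.

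Camera also called 3 lists higher after ethanol at the preset correlation. Of 23 Hox genes, which set position along the body axis, 17 were above control with a mean of 0.12 and an adjusted p of 0.0251, and adjusted p = 0.809 with an estimated correlation. Of 16 genes of the liver bud and gut endoderm 15 were above control with a mean of 0.30, an adjusted p of 0.0251, and adjusted p = 0.809 with an estimated correlation. Of 16 genes of primitive erythroid cells, the first blood cells of the embryo, 13 were above control with a mean of 0.12, an adjusted p of 0.0328, and adjusted p = 0.809 with an estimated correlation. Members changed were 0 over all genes and 0 adjusted over the list alone in each of the 3 lists, with or without the block. With the block these lists did not pass, at adjusted p-values of 0.0901, 0.117 and 0.0901, while the erythroid list passed with the block once replicate 6 was left out (0.0299). In replicates 1 to 6 and 7 to 12 the means were -0.06 and 0.30 for the Hox list, -0.31 and 0.91 for the liver bud and gut list, and 0.07 and 0.18 for the erythroid list. Single pairs carried much of these means: the Hox mean was 0.04 without pair 10, the liver bud and gut mean 0.10 without pair 9 and the erythroid mean 0.05 without pair 8. Without single embryos, chosen after seeing the data, the Hox call was lost without Ethanol 7 (0.333), 8 (0.0854) or 10 (0.363) or Control 6 (0.274), 7 (0.0539), 10 (0.102) or 12 (0.136). The liver bud and gut call was lost without Ethanol 8 (0.45), 9 (0.174) or 11 (0.19) or Control 2 (0.131), 4 (0.0615), 6 (0.14), 9 (0.183), 10 (0.058) or 12 (0.079). The erythroid call was lost without Ethanol 3 (0.116), 4 (0.0989), 5 (0.24), 6 (0.107), 8 (0.0854), 10 (0.16) or 12 (0.198) or Control 1 (0.276), 7 (0.177), 8 (0.506), 9 (0.0825), 10 (0.172) or 11 (0.0704). The liver bud and gut list holds abundant transcripts that the visceral yolk sac also makes, and the visceral yolk sac list stood at 0.16 (SD of pair differences 0.964, adjusted p = 0.492).

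Single genes did not change detectably after ethanol. Of 16927 probes 0 passed in limma, with 177 at an unadjusted p under 0.05 where 846 would be given by chance, and 0 passed with the block, with 784 at an unadjusted p under 0.05. The fit without the block counts the difference between the replicate sets as spread between embryos, which raises its p-values. The genes of smallest p are given as values. Tfap2b, a transcription factor of the neural crest, differed by -0.35 (SE 0.109), Tmem267 by 0.49 (SE 0.146) and Zfp619 by 0.27 (SE 0.0933), each with an adjusted p of 1. The placental hormone genes Prl2c3 and Prl2c4 differed by -1.99 (SE 0.728) and -1.85 (SE 0.686), also with an adjusted p of 1. They are near-identical copies of 1 family whose probes could share signal, and 6 Control, 1 Ethanol and 2 Nicotine embryos reached an intensity of 100 for Prl2c3. In replicates 1 to 6 and 7 to 12 Prl2c3 differed by -0.86 and -3.11.

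Genes that handle alcohol were close to control. Aldh2, which clears acetaldehyde in mitochondria, differed by -0.02 (SE 0.0732), Adh5 by -0.06 (SE 0.103) and Adh1 by -0.14 (SE 0.135). Aldh1a2, which makes retinoic acid, differed by 0.32 (SE 0.162), and Cyp26a1, which degrades it, by -0.15 (SE 0.194). The growth factor gene Igf2 differed by -0.09 (SE 0.0579) and the DNA methyltransferase gene Dnmt1 by -0.05 (SE 0.0738), all at an adjusted p of 1. The list of alcohol and aldehyde metabolism had a mean of -0.02 (adjusted p = 0.494), retinoic acid signalling 0.01 (adjusted p = 0.805), oxidative stress defence 0.02 (adjusted p = 0.88) and p53 targets and apoptosis -0.01 (adjusted p = 0.519).

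**Figure D2:**
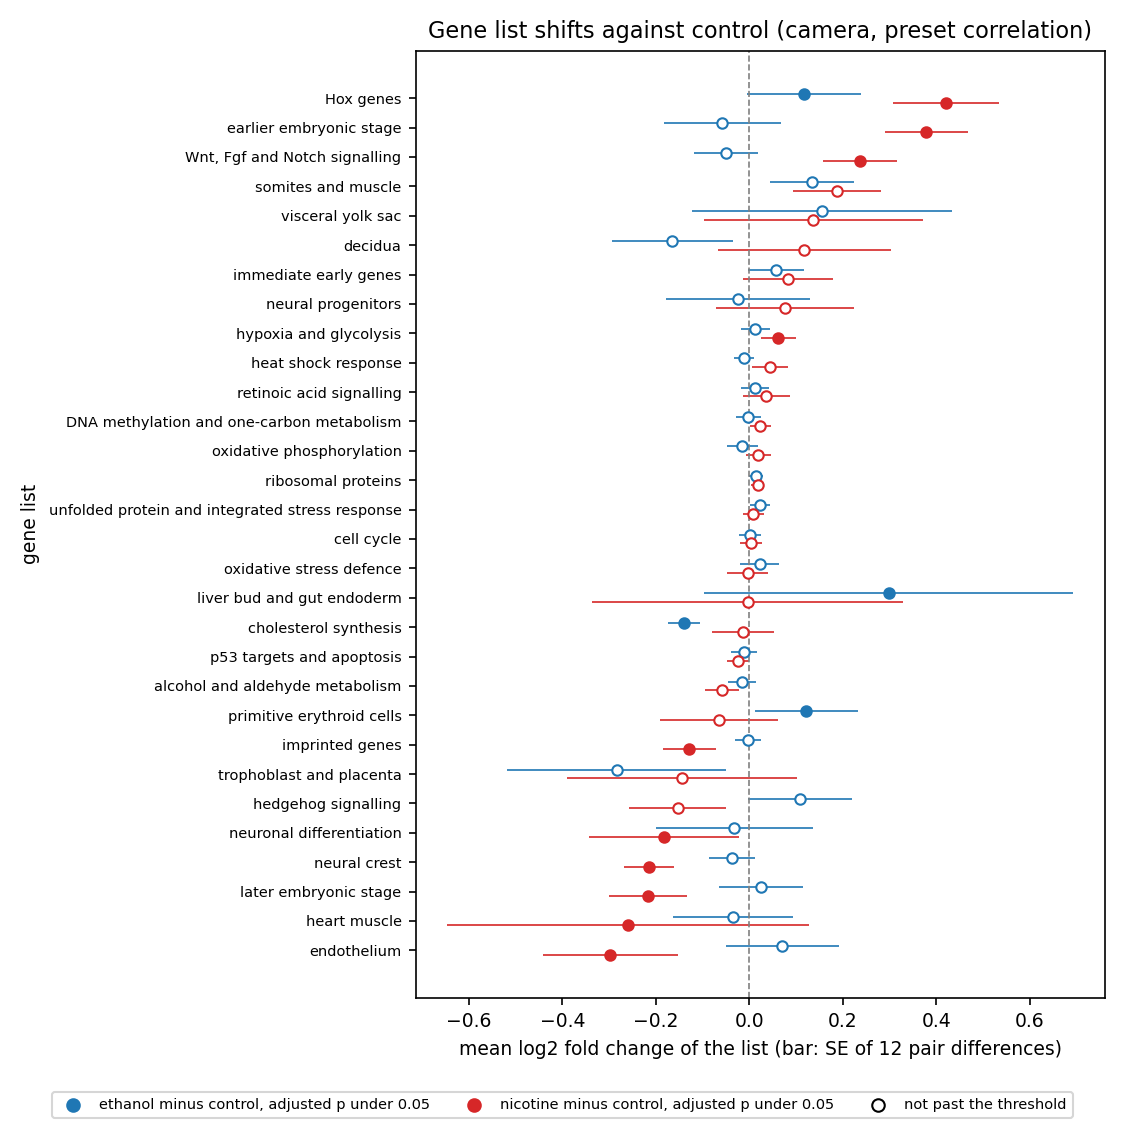
Mean log2 fold change of each of the 30 gene lists (horizontal axis) for ethanol minus control (blue) and nicotine minus control (red), with bars of 1 SE of the 12 pair differences and filled points for lists past an adjusted p of 0.05 in camera at the preset correlation. The cholesterol synthesis list lies at -0.14 after ethanol and the Hox list at 0.42 after nicotine.

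The comparison of nicotine with control asks the same of maternal nicotine. Genes that rose with replicate number as a block are given first (SEs here are of the blocked fit). Hoxc10, a Hox gene of the trunk and tail, rose by 1.497 (SE 0.308, adjusted p = 0.0215), from a mean intensity of 300 to 805, and was higher in 11 of 12 pairs. Cdx2, a regulator of posterior Hox genes, rose by 1.32 (SE 0.306, adjusted p = 0.0334) in 11 of 12 pairs, and Tbx6, needed to form somite mesoderm, by 1.32 (SE 0.289, adjusted p = 0.0273) in 9 of 12. Evx1 rose by 1.18, Nkx1-2 by 1.15, Hoxd9 by 0.95, Hoxd8 by 0.86, Cdx4 by 0.84, Epha5 by 0.82 and Hoxb1 by 0.74, with adjusted p-values between 0.0158 and 0.044. Wnt3a, a Wnt ligand of the tail bud, rose by 0.64 (SE 0.158, adjusted p = 0.0435), and Dusp5, a phosphatase of the MAP kinase pathway, by 0.43 (SE 0.0813, adjusted p = 0.0176) in 12 of 12 pairs. None of these genes passed without the block, where their adjusted p-values ran from 0.216 to 0.502.

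Among the genes that were lower after nicotine in the blocked fit, Dlx1, which patterns the branchial arches, fell by 0.79 (SE 0.184, adjusted p = 0.0334) and was lower in 12 of 12 pairs, and Tfap2b fell by 0.48 (SE 0.103, adjusted p = 0.0264). Its other 3 probes stood at -0.05, -0.43 and -0.27. Ptx3, a secreted pentraxin, fell by 1.04 (SE 0.242, adjusted p = 0.0334), Lamc3, a laminin chain, by 0.80 (SE 0.183, adjusted p = 0.0317), and Pcolce, an enhancer of collagen processing, by 0.55 (SE 0.127, adjusted p = 0.0335). Nnat, an imprinted gene, fell by 0.63, Laptm5 by 0.63, Tspan17 by 0.73, Clmp by 0.61, Rab11fip2 by 0.51 and Serpinf1 by 0.51, with adjusted p-values between 0.0264 and 0.0467. Without the block none of these passed, with adjusted p-values from 0.216 to 0.447.

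**Figure D3:**
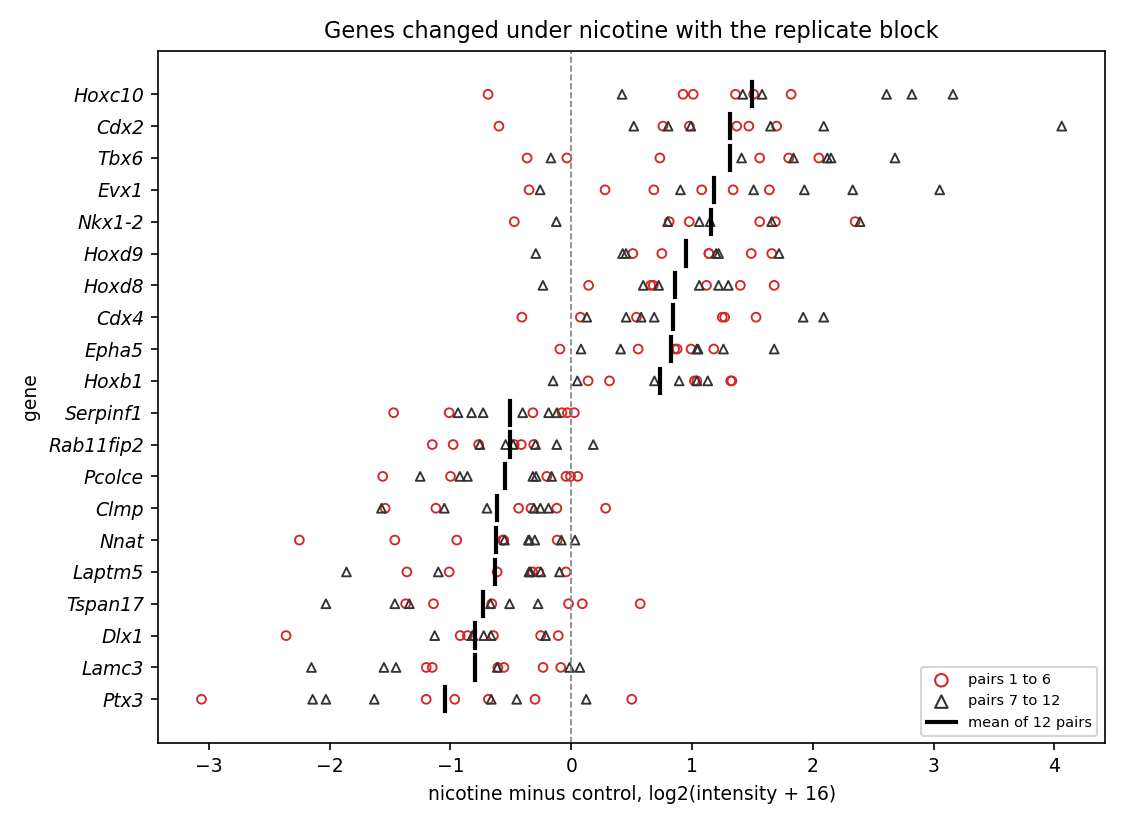
Nicotine minus control difference in log2(intensity + 16) for the 10 genes that rose and the 10 that fell most among those past the threshold with the replicate block; circles are pairs 1 to 6, triangles pairs 7 to 12 and bars the mean of the 12 pairs. Hoxc10 has the highest mean, 1.497, and Ptx3 the lowest, -1.04, and Dlx1 lies below 0 in every pair.

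In number, 1 of 16927 probes changed after nicotine in limma without the block, with 1102 at an unadjusted p under 0.05. It was a probe of Mllt3, a chromatin reader of the transcription elongation machinery, which rose by 0.54 (SE 0.0951, adjusted p = 0.0306) and was higher in 12 of 12 pairs. The other 3 probes of Mllt3 stood at 0.24, 0.03 and -0.12, so the probes disagree, and Mllt3 is named after its values were seen. With the block 194 probes passed, 113 higher and 81 lower, for 148 named genes (83 higher, 65 lower). Without the block the count was 0 when Nicotine 1, 2, 3, 4, 6, 7 or 8 or Control 2, 5, 7, 8, 10, 11 or 12 was left out, 2 without Nicotine 12 and 7 without Nicotine 5. With the block it was 0 without replicate 6, 0 without replicate 7, 1 without replicate 2 and 75 without replicate 10. With the 2 sets as the block, chosen after seeing the data, 3 probes passed, of Mllt3, Rrp1b (0.50) and Nr2f2 (-0.59), and Rrp1b and Nr2f2 are also named after their values were seen. The other 3 probes of Rrp1b stood at -0.20, -0.14 and 0.11, so they disagree.

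As a list fixed in advance, the Hox genes rose after nicotine. Of 23 measured, 20 were above control, with a mean of 0.42 (SD of pair differences 0.393) in 10 of 12 pairs, and camera gave an adjusted p of 3.63e-10. The call was lost with adjusted p = 0.0768 with an estimated correlation. The list passed with fry (adjusted p = 0.0458, and 0.0261 with the block) but not with the exact sign-flip test of the pairs (adjusted p = 0.0635). Over all genes 0 Hox genes passed and 7 adjusted over the list alone, and with the block 5 over all genes and 12 adjusted over the list alone. Hoxc6 (0.63) was the fifth of these 5, beside Hoxb1, Hoxd8, Hoxd9 and Hoxc10. The mean was 0.45 in replicates 1 to 6 and 0.39 in replicates 7 to 12.

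Camera at the preset correlation also called signalling genes higher. Of 26 genes of Wnt, Fgf and Notch signalling 22 were above control, with a mean of 0.24 (SD of pair differences 0.272, camera adjusted p = 5.51e-07), and the call was lost with adjusted p = 0.0625 with an estimated correlation. Over all genes 0 passed and 5 adjusted over the list alone, namely Wnt3a, Axin2 (0.30), Dkk1 (0.33), Wnt1 (0.46) and Sp5 (0.51), the last 3 named after their values were seen. With the block 2 passed over all genes, Wnt3a and Axin2, and 6 adjusted over the list alone. The list of an earlier embryonic stage rose by 0.38 (SD of pair differences 0.309) with 8 of 9 genes above control and a camera adjusted p of 0.000141, and the call was lost with adjusted p = 0.123 with an estimated correlation. In it Wnt3a and Tbx6 made up the 2 members adjusted over the list alone, against 0 over all genes, and with the block they passed both ways. The list of a later stage fell, with 3 of 16 genes above control and a mean of -0.22 (SD of pair differences 0.288, adjusted p = 0.00212), and the call was lost with adjusted p = 0.0768 with an estimated correlation. Its members passed in 0 cases over all genes and 0 adjusted over the list alone, and with the block in 0 and 3, Dcx (-0.71), Col2a1 (-0.17) and Gap43 (-0.25), named after their values were seen. The means in replicates 1 to 6 and 7 to 12 were 0.18 and 0.30 for the signalling list, 0.20 and 0.56 for the earlier list and -0.24 and -0.20 for the later list. The signalling list passed with fry (adjusted p = 0.0246, and 0.0261 with the block). For the earlier and later lists fry gave 0.0742 each, and with the block 0.0281 and 0.0284. The exact sign-flip test passed the earlier list (adjusted p = 0.0439) but not the signalling (0.103) or later (0.152) list.

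The neural crest list fell after nicotine. Of 17 genes 3 were above control, with a mean of -0.21 (SD of pair differences 0.185), lower in 10 of 12 pairs. Camera gave an adjusted p of 1.17e-06 and the call held with adjusted p = 0.00629 with an estimated correlation, but with the block adjusted p = 0.157 with an estimated correlation. The list passed with fry (adjusted p = 0.00506, and 0.0133 with the block) and with the exact sign-flip test of the pairs (adjusted p = 0.0439). Over all genes 0 members passed and 3 adjusted over the list alone, Tfap2b, Dlx1 and Alx4 (-0.39), and with the block 2 over all genes and 4 adjusted over the list alone, the fourth being Prrx1 (-0.46), a gene of limb and face mesenchyme. Alx4 and Prrx1 are named after their values were seen. In replicates 1 to 6 and 7 to 12 the mean was -0.20 and -0.23.

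The imprinted genes, expressed from 1 parental copy, fell as a list by -0.13 (SD of pair differences 0.199), with 3 of 15 above control and a camera adjusted p of 0.00262. The call held with adjusted p = 0.0161 with an estimated correlation, and with the block adjusted p = 0.262 with an estimated correlation. Fry passed it (adjusted p = 0.0196, and 0.0261 with the block) but the exact sign-flip test of the pairs did not (adjusted p = 0.178). Nnat and Peg3 (-0.43, SE 0.141, below control in 12 of 12 pairs) passed adjusted over the list alone, against 0 over all genes. With the block 1 passed over all genes, Nnat, and 7 adjusted over the list alone, 6 lower and 1 higher, Phlda2 (0.84), a growth-restraining gene of the placenta. Peg3 and Phlda2 are named after their values were seen. The mean was -0.22 in replicates 1 to 6 and -0.04 in replicates 7 to 12.

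Endothelial genes were below control as a list. All 16 had a negative mean difference and the list fell by -0.30 (SD of pair differences 0.498, camera adjusted p = 2.73e-07), in 9 of 12 pairs. These genes vary together (estimated correlation 0.64), and the call was lost with adjusted p = 0.309 with an estimated correlation. The list did not pass with fry (adjusted p = 0.254, and 0.158 with the block) or with the exact sign-flip test of the pairs (adjusted p = 0.262). Esam, an endothelial adhesion molecule, stood at -0.45 (SE 0.185) and Robo4 at -0.62 (SE 0.27). Members passed in 0 cases over all genes and 0 adjusted over the list alone, with or without the block. The mean was -0.23 in replicates 1 to 6 and -0.36 in replicates 7 to 12.

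Camera called 3 more lists after nicotine. None of the 3 passed with fry (adjusted p from 0.206 to 0.768) or with the exact sign-flip test (adjusted p from 0.426 to 0.848). Heart muscle genes had a mean of -0.26 (SD of pair differences 1.34), though 7 of 12 pairs were higher, with 2 of 22 genes above control and an adjusted p of 0.00862, and the call was lost with adjusted p = 0.715 with an estimated correlation. This mean came from 1 embryo, Nicotine 3, whose list mean lay -3.75 from the median of its group and set. Without pair 3 the mean was 0.10, and without Nicotine 3 the adjusted p was 0.401. The heart call was also lost without Nicotine 7 (0.0527) or 11 (0.0514) or Control 1 (0.0539), 3 (0.0686) or 8 (0.0666). With all pairs the mean was -0.54 in replicates 1 to 6 and 0.02 in replicates 7 to 12. Genes of neuronal differentiation had a mean of -0.18 (SD of pair differences 0.557, adjusted p = 0.00862), and -0.09 without pair 10, and the call was lost with adjusted p = 0.664 with an estimated correlation and, at the preset correlation, with an adjusted p of 0.134 without replicate 6. Genes of hypoxia and glycolysis had a mean of 0.06 (SD of pair differences 0.129, adjusted p = 0.0297), and 0.04 without pair 6, and the call was lost with adjusted p = 0.336 with an estimated correlation, 0.0524 with the block and 0.158 without replicate 6. Without single embryos the neuronal call was lost without Nicotine 6 (0.0541) or 10 (0.0797) or Control 5 (0.087) or 9 (0.109). The glycolysis call was lost without Nicotine 4 (0.0724), 6 (0.273) or 7 (0.0562) or Control 5 (0.0549), 9 (0.0618), 10 (0.0535), 11 (0.0809) or 12 (0.129). Members of these lists passed in 0 cases over all genes and 0 adjusted over the list alone. With the block 0 passed over all genes and adjusted over the list alone 2 neuronal genes, Dcx and Gap43, and 3 of hypoxia and glycolysis, Aldoa (0.19), Pfkl (0.15) and Egln3 (0.31), passed, named after their values were seen.

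Genes of nicotine's own targets were near the lower limit of the array. Only 4 of 20 genes of the nicotinic acetylcholine receptor list were kept, too few to test as a list. Chrna3 differed by -0.25 (SE 0.201), Chrna4 by 0.06 (SE 0.213), Chrnb1 by 0.03 (SE 0.167) and the receptor chaperone Ric3 by 0.20 (SE 0.0869, its other probe by -0.02), with adjusted p-values between 0.669 and 1. The cholesterol synthesis list, lower after ethanol, had a mean of -0.01 after nicotine (adjusted p = 0.791).

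The comparison of ethanol with nicotine asks whether the exposures differ from each other. Positive values mean higher after ethanol. With the block Barx1, a gene of the first branchial arch and stomach, was higher by 1.07 (SE 0.231, adjusted p = 0.0443) and Msc, a gene of branchial arch muscle, by 1.06 (SE 0.234, adjusted p = 0.0443), in 11 and 10 of 12 pairs. Hoxc10 was lower after ethanol by -1.41 (SE 0.308, adjusted p = 0.0443), Nkx1-2 by -1.35 (SE 0.256, adjusted p = 0.0291), Cdx4 by -1.14 (SE 0.201, adjusted p = 0.0198) and Epha5 by -0.97 (SE 0.151, adjusted p = 0.0125). In number, 0 of 16927 probes passed in limma without the block (834 at an unadjusted p under 0.05). With the 2 sets as the block, chosen after seeing the data, the count was also 0. With replicate number as the block 69 passed, 36 higher and 33 lower after ethanol, for 54 named genes. Of the 194 probes of nicotine against control and these 69, 44 were the same, and in all 44 nicotine stood apart from both other groups in 1 direction. Both comparisons use the same nicotine arrays, so an overlap is built in. Without the block 12 probes passed without Nicotine 5, 3 without Nicotine 11, 2 without Nicotine 12 or Ethanol 7 and 1 without Nicotine 9. With the block the count ran from 0 without replicates 2, 6 or 8 to 178 without replicate 5, with 3 without replicate 4, 8 without 9, 9 without 1, 11 without 12, 31 without 3, 32 without 7, 41 without 10 and 103 without 11.

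Of 30 lists 14 differed between ethanol and nicotine, 8 higher and 6 lower after ethanol, and 4 of these held with an estimated correlation. Wnt, Fgf and Notch signalling was lower by -0.29 (SD of pair differences 0.231) in 12 of 12 pairs, with an adjusted p of 6.15e-11 and adjusted p = 0.0187 with an estimated correlation. The earlier stage list stood at -0.44, the neural crest list at 0.18 and the imprinted list at 0.13, each with adjusted p = 0.0276 with an estimated correlation. With the block adjusted p = 0.176 with an estimated correlation for the signalling, earlier stage and neural crest lists and 0.226 for the imprinted list. These 4 lists passed with fry (adjusted p from 0.0154 to 0.0222, and from 0.0128 to 0.0312 with the block). In the exact sign-flip test the signalling (adjusted p = 0.0146), neural crest and imprinted (0.0488 each) lists passed and the earlier stage list did not (0.0623). The call was lost for endothelium (0.37, 16 of 16 higher) with adjusted p = 0.133 with an estimated correlation, for Hox genes (-0.30) with adjusted p = 0.206 with an estimated correlation, and for cholesterol synthesis (-0.13, 14 of 15 lower) and the later stage (0.24) with adjusted p = 0.106 with an estimated correlation. It was lost for hedgehog signalling (0.26) with adjusted p = 0.342 with an estimated correlation, and for erythroid cells (0.19), the liver bud and gut list (0.30) and neural progenitors (-0.10) with adjusted p = 0.513 with an estimated correlation. For decidua (-0.28) and heart muscle (0.22) it was lost with adjusted p = 0.235 and adjusted p = 0.736 with an estimated correlation. In replicates 1 to 6 and 7 to 12 the means were -0.51 and -0.09 for Hox genes, -0.18 and 0.78 for the liver bud and gut list, 0.50 and -0.05 for heart muscle, -0.04 and -0.16 for neural progenitors, 0.17 and 0.08 for imprinted genes and -0.37 and -0.20 for decidua. They were -0.32 and -0.26 for signalling, -0.46 and -0.41 for the earlier stage, 0.20 and 0.29 for the later stage, 0.20 and 0.15 for the neural crest, 0.33 and 0.41 for endothelium, -0.13 and -0.13 for cholesterol synthesis, 0.27 and 0.26 for hedgehog signalling and 0.19 and 0.19 for erythroid cells. At the preset correlation the block also lost the liver bud and gut list (0.0727), decidua (0.0542), heart muscle (0.0542, but 0.00859 without replicate 6) and neural progenitors (0.133). It gave neuronal differentiation (0.15) an adjusted p of 0.0327, lost with adjusted p = 0.702 with an estimated correlation and with 0.0843 without replicate 6, and without the block decidua was lost without replicate 6 (0.173). Without single embryos the neural progenitor call was lost without Ethanol 1 (0.153), 2 (0.0881), 5 (0.113) or 8 (0.0674) or Nicotine 7 (0.121), 8 (0.0739), 9 (0.0931) or 11 (0.185), and the heart call without Ethanol 1 (0.133), 2 (0.0922) or 5 (0.0951) or Nicotine 7 (0.121) or 11 (0.126). The mean of the heart list was -0.04 without pair 3, that of the liver bud and gut list 0.11 without pair 8, that of neural progenitors -0.06 without pair 1 and that of decidua -0.16 without pair 6. The erythroid call was lost without Ethanol 5 (0.0571) or Nicotine 2 (0.0524) or 11 (0.107), the liver bud and gut call without Ethanol 8 (0.127), 9 (0.0904) or 11 (0.0717) or Nicotine 6 (0.115), and the decidua call without Nicotine 6 (0.0922).

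Members of these lists passed in 0 cases over all genes without the block. Adjusted over the list alone, 4 signalling genes were lower after ethanol, Wnt3a (-0.67), Axin2 (-0.30), Etv4 (-0.39) and Sp5 (-0.54), and 4 of the earlier stage, Wnt3a, Tbx6 (-1.17), Dnmt3b (-0.17) and Otx2 (-0.62), a regulator of the forebrain. Adjusted over the list alone, 2 genes of the neural crest were higher, Snai2 (0.33) and Dlx1 (0.59), and 1 imprinted gene, Peg3 (0.51), while Alpl (-0.37) of the decidua list and Gbx2 (-0.66) of the neural progenitors were lower. The genes named here, with and without the block, were chosen after their values were seen. With the block Axin2, Hoxc10 and Gbx2 passed over all genes, and adjusted over the list alone 6 signalling genes, 11 Hox genes, 12 endothelial genes, the same 4 genes of the earlier stage, 4 of the neural crest (with Ets1, 0.44, and Prrx1, 0.42), 3 of cholesterol synthesis (Mvd, Lss and Fdps, lower after ethanol, where Lss stood at -0.24 and its other probe at 0.02, so the probes disagree), 2 imprinted genes (with Cdkn1c, 0.21) and 2 of decidua (with Prf1, -0.43). Adjusted over the list alone, 1 gene each passed with the block from the hedgehog (Foxf1, 0.62), erythroid (Rhag, 0.50), liver bud and gut (Cdx2, -1.20) and neural progenitor (Gbx2) lists.

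**Figure D4:**
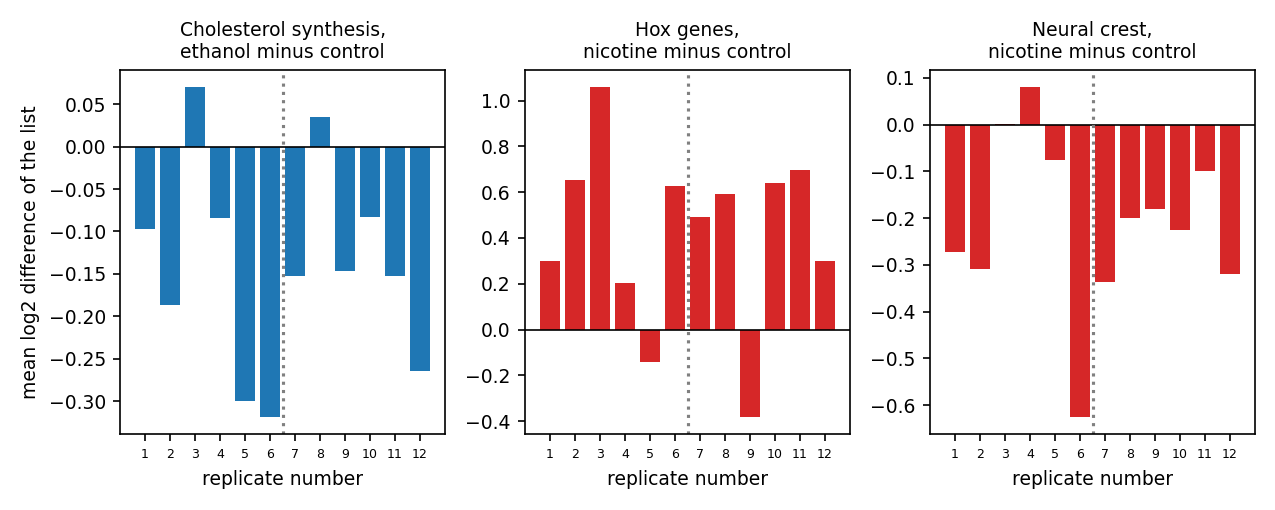
Mean log2 difference over the list (vertical axis) in each of the 12 pairs of equal replicate number, for cholesterol synthesis after ethanol, Hox genes after nicotine and the neural crest list after nicotine; the dotted line parts replicates 1 to 6 from 7 to 12. The cholesterol list is below 0 in 10 of 12 pairs and the Hox list above 0 in 10 of 12.

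Embryos of an exposed group did not differ detectably more among themselves than control embryos. The mean distance of an embryo from the rest of its group was 0.385 ± 0.0493 (SD) after ethanol and 0.38 ± 0.0604 in Control, a difference of 0.005 (permutation test, two-sided, p = 0.83). After nicotine it was 0.428 ± 0.068, a difference of 0.0483 (p = 0.0788). With only the means of the sets removed the difference was 0.0242 (p = 0.426). With the replicate means removed it was 0.00333 (p = 0.864). That removal shares each embryo's deviation with the embryos of its number in the other groups, which by itself shrinks a difference in spread.

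Fold changes after ethanol and after nicotine correlated with r = 0.311 across 9683 genes, which are not independent replicates. Both use the same 12 control embryos, and unchanged groups against shared controls gave a mean r of 0.524 in 100 draws (range 0.153 to 0.813). The covariance was 0.00446 against 0.00583 simulated, a difference of -0.00137, and the share of genes with the same sign was 63% against 67.8%. With the controls split 6 against 6, r was -0.0941 and the covariance -0.00264.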

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

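The tests of head tissue, of the replicate sets and of replicate 6 and the fits with stage as a covariate were chosen only after the result was seen, and the test of embryonic stage after the shifts of the lists themselves had been seen.

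Xist, the RNA that silences an X chromosome in female cells, drew attention because it was outside the comparisons and above every control embryo in Ethanol 1, whose label is male. Its 4 probes read 31, 34.7, 52.4 and 37.8 there, against highest control intensities of 5.59, 6.02, 10.1 and 18.6. The Y-linked genes Eif2s3y and Kdm5d were also present in that embryo, at 720 and 175.

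After nicotine, camera at the preset correlation called the Hox, signalling and earlier-stage lists higher and the neural crest and endothelial lists lower, and of these 5 calls those of the Hox (adjusted p = 0.0768), signalling (0.0625), earlier-stage (0.123) and endothelial (0.309) lists were lost with an estimated correlation, and with the block all were, at 0.157 to 0.439. Across 76 genes of the Hox, signalling, neural crest and endothelial lists that are in neither stage list, the nicotine difference correlated at -0.799 with the slope of each gene on a stage score among ethanol embryos, where 5 of 100 swaps of labels within pairs went as low, and at -0.387 over 9658 genes, where 4 of 100 did, so an earlier stage of the nicotine embryos stays open and cannot be told apart from chance differences in stage, as the 76 genes come from lists that had shifted. The stage score, later minus earlier list, was -0.468 ± 0.531 (SD) in nicotine and 0.129 ± 0.43 in control embryos, lower in 10 of 12 pairs. An exact sign-flip test of the pairs gave p = 0.00293 for nicotine and p = 0.651 for ethanol against control. The score restates the shifts of the stage lists and is no separate evidence. Loss of head tissue would lower forebrain and midbrain genes, and 8 of them had a mean of 0.341 (SE 0.195) above control. That mean was not clear of 0, and Otx2 (0.373) and Wnt8b (0.622) among them are members of the lists that had risen. The values argue against a fall as large as that of the neural crest list. A loss beside an earlier stage cannot be told apart. A shift in 1 set alone or in replicate 6 is argued against as the whole cause for these lists at the preset correlation alone, since 5 of 5 kept their direction in both sets and passed camera with the block without replicate 6. The count of single probes with the block fell from 194 to 0 without replicate 6. It also fell to 1 without replicate 2, so the fall is not particular to replicate 6. A direct effect of nicotine, the difference the design names, stays open too, since with the stage score as a covariate the neural crest list went from -0.223 (SE 0.0505) to -0.159 (SE 0.0603) and the endothelial list from -0.297 (SE 0.138) to -0.0405 (SE 0.151), but the score itself differs between the groups.

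After ethanol, cholesterol synthesis genes were lower. Each set of replicates holds equal numbers of embryos of every group, so a difference between the sets cancels from this shift by design. A shift in 1 set alone is argued against, since the mean was -0.153 (SE 0.06) in replicates 1 to 6 and -0.128 (SE 0.0402) in 7 to 12. A few embryos are argued against, since without the 2 pairs of largest fall the mean was -0.106. Random lists matched on level had a mean of 0.00707, and 15 of 10000 were as low. They cannot decide on a normalization effect on probes of this brightness. The arrays had nearly equal distributions, which by itself holds the mean difference of genes of similar level close to 0. The random lists hold unrelated genes, while the cholesterol genes vary together (estimated correlation 0.15). The 15 of 10000 is therefore no measure of chance for this list. An effect of maternal ethanol on this pathway is a candidate explanation, found and tested on the same embryos, for a list that did not pass with fry (adjusted p = 0.435).

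Replicates 1 to 6 and 7 to 12 differed at most probes. The set difference of the 2 brightest probes of a gene correlated at 0.128 over 3513 genes, against 0.587 for the main deviation within sets, which is consistent with a technical difference specific to single probes. Across genes the set difference correlated with the stage slope at 0.133, below the bound of 0.2 set beforehand, and 9 of 100 permutations were as large. This argues against stage as the main source of the set difference. A smaller difference in stage stays open, since the correlation of 0.128 between probes of a gene limits the correlation with any slope. Stage was the 1 biological explanation tested, and the design names no group that goes with the sets.

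Other splits of the arrays were drawn to see whether chance can be excluded. Where the real count of probes was 0 the splits decide nothing, since 100 of 100 reach 0 by construction; this holds for ethanol against control (highest other 0) and ethanol against nicotine (highest other 1). For ethanol against control chance cannot be excluded for the lists, as 57 of 100 splits gave as many as the real 4 (highest other 13). For nicotine against control 3 of 100 splits gave as many probes as the real 1, but the highest other gave 72. These splits can part the replicate sets unequally. Swaps of labels within pairs keep the sets balanced, and without the block their highest other gave 1 probe. Of these swaps 2 of 100, the real grouping among them, gave as many probes as the real 1. As many lists as the real 10 came from 14 of 100 splits (highest other 12). For ethanol against nicotine 2 of 100, the real one among them, gave as many lists as the real 14. The highest other gave 15, more than the real grouping, so chance seldom reached that count but is not excluded. Swaps within pairs without the block reached the real count of lists in 85 of 100 cases for ethanol against control. They did so in 33 of 100 for nicotine against control and 3 of 100 for ethanol against nicotine.

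With the block, labels were swapped within pairs, so each swap parts as many pairs as the real grouping. For nicotine against control 1 of 100, the real one, reached 194 probes (highest other 41), and for ethanol against nicotine 1 of 100, the real one, reached 69 (highest other 2). Chance is thus unlikely for both counts of probes, but 100 swaps cannot resolve a share below 1 of 100. Chance is not excluded for the counts of lists, where 28 of 100 swaps reached the real 9 after nicotine (highest other 12) and 10 of 100 the real 11 between ethanol and nicotine (highest other 14).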

How the results depend on the processing

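The settings without an offset, with the strict filter, with the sets or replicate 6, with the random block and with the sign-flip test were chosen only after the data were seen. For ethanol against control the count of probes was 0 in limma under every setting run and without any 1 embryo. For nicotine vs control: probes changed were 1, and 0 with cyclic loess, no filter, array weights, 1 probe per gene, the filter of 100 on all arrays, only replicates 1 to 6, only 7 to 12, or only the 24 arrays compared, 3 with the sets as a block, 112 (46 higher, 66 lower) with the first residual component as a covariate, 194 with the replicate block and 350 (178 higher, 172 lower) with replicate as a random block. At an unadjusted p under 0.05 the settings with 0 gave 576 to 2623 probes. With the replicate block it was 194, 1, 131, 204, 231, 0, 0, 152, 256, 75, 147 and 146 as replicates 1 to 12 were left out in turn. For ethanol vs nicotine: probes changed were 0, and 69 with the replicate block, 3 (Mllt3, Baz2b and Plpp3) with the residual component, 150 with the random block and, with the replicate block, 9, 0, 31, 3, 178, 0, 32, 0, 8, 41, 103 and 11 as replicates 1 to 12 were left out in turn. The cause was not tested.

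Called lists numbered 4, 10 and 14 for ethanol, nicotine and ethanol against nicotine. They were 1, 2 and 4 with an estimated correlation, 0, 4 and 4 with fry, 0, 2 and 3 with the exact sign-flip test of pairs, 1, 1 and 0 with the sets as a block and an estimated correlation, and 0, 0 and 0 with the replicate block and an estimated correlation. For ethanol the count was 1 with no filter, the replicate block, the residual component, the filter of 100, or the sets as a block, and it was 4 without replicate 6 and 2 with the block without it. It was 8 and 9 for nicotine and 14 and 11 between the exposures without replicate 6, without and with the block. With the filter of 100, 8 lists differed between ethanol and nicotine. In the sign-flip test the cholesterol list had an exact p of 0.00342 and an adjusted p of 0.103. The cause was not tested.

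The difference in spread after ethanol turned from 0.005 to -0.000747 with the median absolute deviation, -0.0159 with the replicate block, -0.0226 without the residual component and -0.0282 without set means, and did not pass in any of these. The correlation of fold changes turned to -0.0941 with the controls split. Of 239 named values, Chrna3 after ethanol turned from -0.07 to 0.0246 with no offset, 50 that did not pass without a block passed with the replicate block and 17 with the residual component. The replicate block changed no list call at the preset correlation beyond those named with the lists. Alternatives not run were those that need detection values, control probes or slides. Dim probes limit what can be seen: 16927 of 45281 probes passed the intensity filter.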

Other observations

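The gene groups described here were chosen after their values were seen, and the covariate fits of stage were chosen only after the result was seen.

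Single embryos stood far above their groups for Ttr and Apoa1. Ttr, which carries thyroid hormone, had a median intensity of 190 in Control, 331 in Ethanol and 214 in Nicotine, and reached 6710 in Control 3, 4850 in Ethanol 8 and 9390 in Nicotine 1. Apoa1, the main protein of high-density lipoprotein, reached 4760, 5140 and 8420 in the same 3 embryos, against group medians of 74.9, 79 and 67.6. The placental hormone gene Prl2c2 was at or above an intensity of 100 in 8 Control, 2 Ethanol and 5 Nicotine embryos and reached 14900 in Control 3.

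The 3 embryos numbered 6, 1 per group, had low levels of several groups of genes, among them those of mitochondrial energy production. Their list of 27 oxidative phosphorylation genes lay at -0.62 against replicates 1 to 5 on the log2 scale (-0.69 to -0.53 over the 3), where those ranged from -0.16 to 0.17. Slirp, a mitochondrial RNA-binding protein, had a mean intensity of 682 in them and 2670 in replicates 1 to 5. The ribosomal protein list lay at -0.14 (-0.17 to -0.10, against -0.05 to 0.06 in replicates 1 to 5), and the histone genes H2ac21 and H2ac8 at -1.49 and -1.48, so the difference was not limited to mitochondrial genes, and RNA quality and probe behaviour were not tested. The oxidative stress defence list lay at -0.32 and the cell cycle list at 0.17.

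In Nicotine 3 the 22 heart muscle genes lay together at -3.75 from the median of the nicotine embryos of its set, and pair 3 differed by -4.20 from its control. The cause was not tested.

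Between the sets of replicates the lists moved unequally. In replicates 7 to 12 the trophoblast and placenta list lay at -0.47, the heat shock list at -0.35 and the liver bud and gut list at 0.31 relative to replicates 1 to 6, while the Hox list lay at -0.00211 and the ribosomal protein list at -0.00435.

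With the stage score as a covariate in the blocked fit, list means over genes outside the stage lists moved as follows. After nicotine the Hox list went from 0.47 (SE 0.127) to 0.29 (SE 0.149), the endothelial list from -0.30 (SE 0.138) to -0.04 (SE 0.151) and the signalling list from 0.23 (SE 0.0706) to 0.09 (SE 0.0773). The neural crest list went from -0.22 (SE 0.0505) to -0.16 (SE 0.0603) and the imprinted list from -0.13 (SE 0.0441) to -0.16 (SE 0.0557). The cholesterol list after ethanol stood at -0.14 (SE 0.0525) before and -0.14 (SE 0.054) after.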
